A study of Mus musculus with 44 samples.

How the data were processed

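The series holds 44 mouse samples: 26 bulk RNA libraries, 16 ATAC libraries and 2 single-cell RNA libraries. The bulk RNA came from 8 GTML and 6 GTS tumors and from 2 cultured tumor lines, GTML3 and preGTS1, each given DMSO or DOX with 3 samples per condition. ATAC-seq, which reads open chromatin by transposase insertion, was done on duplicates of GTML3 and preGTS1 under both conditions, of the sources labelled GTS1 and GTS2, and of the fractions labelled GFP and nonGFP. Per the labels' protocols, RNA was extracted with Trizol and RNeasy columns, bulk RNA libraries were made for Ion Torrent sequencing, and single cells were captured with 10x Chromium 3' chemistry. The submitters' processing notes name STAR 2.4.0, Bowtie2 2.2, Subread 1.5.2, limma, Cell Ranger 3.3.0, Seurat 3.0, MACS2 and edgeR, and the builds mm9 and mm10, without saying which served which table. Groups and replicate numbers came from the sample titles. The title of each treated-line RNA sample is the name of its column, while its free-text description names the next column, so the titles were followed. No column of per-sample values was left unused.

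The bulk RNA tables deposited by the authors hold log2 CPM (counts scaled to library size) per gene symbol, with no gene coordinates. Their column names for the tumors carry a number, 120 or 263, which was read as a batch and splits the tumors as the spelling of their titles does. Batch 120 holds 6 GTML and 2 GTS tumors and batch 263 holds 2 GTML and 4 GTS tumors. In the deposited log2 values the batch coefficient, with tumor kind in the model, was at most 1.8e-14 for any gene, so a mean difference between batches had been removed while keeping tumor kind. The errors of a model without a batch term are then too small, and the sequencing depth of the tumors could not be recovered. In the treated-line table, 2 to the power of the deposited log2 value rose in whole steps per library, which gave whole reads for 100% of the values within a tolerance of 0.1 read. The ATAC tables deposited by the authors hold CPM per region, scaled to the reads in the listed regions, and gave whole reads in the same way. Both name the nearest gene starts with their distances, carry coordinates that fit mm9, and hold 1 line naming no region, which was left out. The single-cell tables deposited by the authors hold whole UMI counts per gene and cell, where a UMI tags 1 captured molecule.

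Depth from the recovered reads was 10.861 to 24.672 M reads per treated-line RNA library. In the listed regions the ATAC libraries held 0.827 to 7.773 M reads for the lines and GTS sources and 8.964 to 14.954 M reads for the GFP and nonGFP fractions. Intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules. Before replicates were averaged, their reads were compared by chi-square. For RNA, the chi-square per degree of freedom between 2 replicates was 4.67 to 85.1, and replicate 1 of GTML3 under DOX stood apart from the other 2 (60.4 and 85.1). For ATAC it was 1.88 to 2.05 in every pair, flat over depth, where independent reads would give about 1. Such values would arise if each fragment were counted 2 times with no other spread, which was not tested. Exact intervals on ATAC reads, which take reads as independent, are then too narrow. On this reading the duplicates differed little beyond counting noise, and ATAC p-values measure little else. The duplicates were merged and counted as 1 sample per condition when CPM and folds were given, and tests on them compare libraries, not conditions. No label says that replicates came from separate cultures or animals, apart from the tumors' own numbers, so p-values measure the spread between these samples, which may be technical.

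Expression and accessibility were tested with limma 3.58.1 (lmFit, then eBayes with trend and robust) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 CPM values were used as deposited, although the plan had expected CPM. ATAC was tested on log2(CPM + 1), which understates the folds of weak regions. Genes needed a CPM of at least 1 in at least 6 tumors or 3 treated-line samples, which left 15708 of 16078 genes in the tumors and all 15926 in the lines. The 4 treated groups shared 1 fit, the 6 groups of the ATAC table of 88981 regions another, and the GFP table of 88258 regions its own. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Promoters were regions within 1 kb of a start, and a list's median promoter change was placed among 10000 random lists matched on level. These percentiles were not adjusted over the lists tried. Beside a group with 0 reads, folds are lower bounds against 3 reads over the whole group. Differences between responses are given as fitted, also beside 0 reads. Replicates, comparisons, gene lists, cell type markers, thresholds and the rule for naming genes were fixed before the data were examined.

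Named genes are Sox9, Mycn, Myc, Mgmt and Slc1a2 in every RNA comparison, the 6 largest changes each way among called genes with CPM of at least 5 in the higher group and ranges that did not overlap, and the 3 members with the smallest p of each called list. For the difference between responses the range condition was dropped. Predicted genes, Riken clones, and ribosomal protein, mitochondrial and microRNA genes, by the start of their names, were left out of the largest changes. For ATAC, the 5 largest gains and losses among regions with a mean above the median region were listed, with all regions within 10 kb of the start of Sox9, Mycn, Myc and Mgmt. The plan had also named their gene bodies, but regions further from the start were not searched. For single cells, the same rule took the 8 largest ratios each way among genes with at least 200 UMIs in the higher library. Names taken outside this rule are marked where they appear, and some genes and regions that the rule chose are not reported here. Genes are named by symbol as the tables give them, and a RefSeq table of the build GRCm38.p6 served only for which genes lie within others.

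Single cells were processed with scanpy 1.11.5 and leidenalg 0.10.2: 2000 variable genes, 30 principal components, 15 neighbours and resolution 1. The 4645 and 4498 cells in the tables equal the numbers the series text states, and every deposited cell was kept. A cluster took a class name, with the suffix "-like", from at least 3 markers of that class among its 30 leading genes by fold, over a pseudocount of 5 CPM. Scrublet marked 1 and 4 cells as doublets (0.02% and 0.09%), so the caller did not work here and doublets were kept. To compare shares of cells with a UMI, cells were thinned to 3000 UMIs. A cell counted as cycling with at least 3 of 14 cycling markers. With 1 library per kind there is no test between the libraries: shares carry exact binomial and sums exact Poisson 95% intervals.

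The statistics were tested on simulated data with 100 genes changed at each of 2 sizes. Changed tumor genes were drawn only from those with a residual SD under 1. Changed treated-line genes were drawn above a minimum of mean reads, and changed regions from those at or above the median level. Recovery of noisier tumor genes, or of weaker genes and regions, was not simulated. For the tumors, limma without a batch term recovered 49% of 2-fold and 94% of 4-fold changes, and 26 of its 169 calls (15.4%) were unchanged genes. With a batch term it recovered 32% and 84%, and 1 of 117 calls (0.9%) was an unchanged gene. For GTML3 RNA it recovered 63% of 1.5-fold and 89% of 2-fold changes, with 9 of 161 calls (5.6%) unchanged. For ATAC, simulated fragments were counted 2 times each, with no further spread. ATAC tests recovered 17% of 2-fold and 49% of 4-fold changes in GTML3, where 81 of 147 calls (55.1%) were unchanged regions, and 14% and 39% in preGTS1, with 0 of 53. Alternatives tried were other pseudocounts and filters, quantile and median scaling, limma without trend, a batch term, each batch alone, a replicate block, each library left out, and edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads. For single cells, other resolutions, depths and cell filters were tried. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.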

Results

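RNA, open chromatin and single cells were measured in mouse medulloblastoma, a tumor of the cerebellum. The GTML model carries a MYCN transgene under a tetracycline-controlled promoter driven from the glial glutamate transporter gene Glt1 (Slc1a2), and GTS tumors arise in a related model in which expression is driven from Sox9. The series title concerns dormant SOX9-positive cells and recurrence, and the comparisons ask how GTS tumors differ from GTML tumors and what DOX does to a GTML line and to the line labelled preGTS1. Bulk RNA covered 8 GTML and 6 GTS tumors, in which Pearson correlations between libraries ran from 0.536 to 0.944. The treated lines had 3 samples each, with 15.56 to 20.718 M reads for GTML3 under DMSO, 10.861 to 16.688 under DOX, 23.967 to 24.672 for preGTS1 under DMSO and 16.371 to 17.509 under DOX. In the listed regions, the duplicate ATAC libraries of GTML3 held 1.671 to 1.748 M reads under DMSO and 0.827 to 0.969 under DOX, and those of preGTS1 6.762 to 7.773 and 5.848 to 6.58. The GTS libraries held 2.085 to 3.997 for GTS1 and 1.185 to 1.658 for GTS2. The single-cell libraries held 4645 cells labelled GTML_SOX9GFP (median 18744 UMIs and 4255 genes per cell) and 4498 cells labelled fGTS2 (20893.5 and 4169).

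GTS tumors were first compared with GTML tumors. Cadps2, which primes secretory vesicles for release, stood at 8.53 ± 1.28 log2 CPM in GTS tumors and 3.38 ± 0.582 in GTML tumors (SD, n = 6 and 8), a log2 fold change of 5.15 (SE 0.474, limma adjusted p = 0.000374). Also higher were Atp2a3, an endoplasmic reticulum calcium pump (5.09), Hepacam2 (4.95), Olfm3 (4.62) and the simple-epithelium keratin Krt8 (4.43, SE 0.803). That the ranges of the genes named in this paragraph do not overlap between tumor kinds follows from the rule for naming. Rnf148 was higher by 6.56, but it lies within Cadps2 and the files do not show which gene its reads came from. Lower in all GTS tumors than in any GTML tumor were the nuclear receptor gene Nr1h5 (-4.29, SE 0.477, adjusted p = 0.00136), the netrin receptor gene Dcc (-3.49, SE 0.698), Fgd1 (-3.37), Foxp3 (-2.84), the corepressor gene Rcor2 (-2.26) and the histone gene Hist1h4f (-2.11).

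The genes behind the model did not pass the limma test in the tumors. Sox9 stood at 4.28 ± 1.2 log2 CPM in GTS and 2.55 ± 0.971 in GTML tumors (log2 fold change 1.73, SE 0.562, adjusted p = 0.0778), and 2 of 6 GTS tumors lay above all GTML tumors. The difference was 1.47 in the batch of 8 tumors and 2.02 in the batch of 6. Mgmt, which removes alkyl groups from guanine in DNA and counters alkylating drugs, stood at 3.17 ± 1.43 and 1.24 ± 0.886 (1.93, adjusted p = 0.0718; 5 of 6; 1.64 and 2.25 by batch). Mycn stood at 7.0 ± 0.579 and 7.63 ± 0.283 (-0.63, adjusted p = 0.0956; -0.69 and -0.57 by batch), and its values do not separate the transgene from the mouse gene. Myc differed by -2.66 (adjusted p = 0.121), with -4.85 in the batch of 8 and -0.19 in the batch of 6, and Slc1a2 by -0.04 (adjusted p = 0.941).

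Of 31 interferon response genes, 15 were higher in GTS tumors and 0 lower (24 and 0 when adjusted over the list alone), with a median log2 fold change of 2.2, including Usp18 (2.80) and Ifi44 (3.68). In the same tumors the myeloid marker Itgam was higher (1.98), and 4 T and NK cell markers had a median of 1.66 (camera adjusted p = 0.287). Of these 0 were higher and 1 lower, Cd4 (-1.39, limma adjusted p = 0.0393; named after its value was seen), and 3 higher and 1 lower over the list alone. Of 35 ribosome biogenesis and MYC target genes, 11 were lower and 0 higher (26 lower over the list alone), such as the pyrimidine synthesis gene Cad (-0.93), Utp20 (-0.81) and Tbrg4 (-0.61). Of 42 S-phase genes 7 were lower (28 over the list alone), among them Dtl (-1.38) and Ung (-1.23), and of 46 G2/M genes 4 were lower (36 over the list alone), among them Hjurp (-0.86), Cenpf (-0.97) and Birc5 (-1.07). Of 29 DNA repair and drug resistance genes, 2 were lower, among them the checkpoint kinase gene Chek2 (-1.16), while 2 higher and 10 lower passed over the list alone. Of 35 astroglial genes of the SOX9 program, 5 were higher and 1 lower (9 and 1 over the list alone), with the astrocyte gene Aldoc (2.17) higher and the progenitor gene Msi1 (-1.57) lower.

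Further lists held few called genes. Of 20 lysosome and autophagy genes 3 were higher, Sqstm1 (0.61), Psap (0.50) and Gabarapl1 (0.64), and of 25 genes on the mitochondrial translation list 2 were lower, Mrpl37 (-0.81) and Hspe1 (-0.55). That list also holds mitochondrial protein folding and import genes, such as Hspe1, Hspd1 and Timm10. Of 19 NF-kB genes only Traf1 passed (2.65). Of 20 microglia and macrophage markers only Itgam passed (1.98), while Ctss differed by 1.23 (adjusted p = 0.068) and P2ry12 by 0.99 (adjusted p = 0.108). No member passed among 16 oligodendrocyte genes (Mag 3.06, adjusted p = 0.0659), 20 photoreceptor genes of the Group 3 subtype (Nrl -3.31, adjusted p = 0.0602; Otx2 -3.48, adjusted p = 0.0627) or 15 antigen presentation genes (B2m 1.18, adjusted p = 0.0864). Over the list alone, 5 oligodendrocyte genes were higher and 2 photoreceptor genes lower. Endothelial, mural, ependymal, erythroid and muscle markers had list medians of -0.03, 0.11, 0.79, 0.69 and -0.33 and were not called as lists. Camera at the preset correlation called 13 of 30 lists. The adjusted p was 3.82e-14 for interferon, 2.234e-13 for ribosome biogenesis, 2.641e-12 for G2/M and 9.079e-12 for S-phase genes. The others were the DNA repair (adjusted p = 0.00049), astroglial (0.00113), NF-kB (0.0115), oligodendrocyte (0.0127), microglia (0.0145), antigen presentation and mitochondrial translation (0.0348 each), lysosome (0.0436) and photoreceptor lists (0.0487). None of these calls held with an estimated correlation. The adjusted p was then 0.425 for interferon and ribosome biogenesis and 0.484 for S-phase, G2/M, DNA repair, astroglial, NF-kB, oligodendrocyte and lysosome genes. It was 0.686 for mitochondrial translation, 0.72 for microglia, 0.731 for antigen presentation and 0.768 for photoreceptor genes.

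In all, limma called 924 of 15708 genes, 616 higher and 308 lower in GTS, while median-centred values gave 428 higher and 86 lower (83.3% higher, against 66.7%) and moved the median gene from -0.075 to 0.031. With a batch term, which restores the error removed with the batches and leaves the folds as they are, 9 genes passed, 8 higher and 1 lower (3067 at unadjusted p under 0.05). Among them were Rnf148 (adjusted p = 0.023), Cadps2 (0.00366) and Nr1h5 (0.0112), but no other gene named here, for which the adjusted p with the batch term was 0.0609 or more. The calls on Cd4, Fgd1, Foxp3, Rcor2, Hist1h4f, Cenpf, Birc5, Gabarapl1, Hspe1 and Aldoc were each lost when some single libraries were left out (6 to 12 of 14). Without GTML tumor 2, 3 or 8 the count was 511, 509 or 571, without GTS tumor 1, 4, 5 or 6 it was 299, 294, 110 or 302, and without GTS tumor 2 or 3 it was 1404 or 1530.

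**Figure D1:**
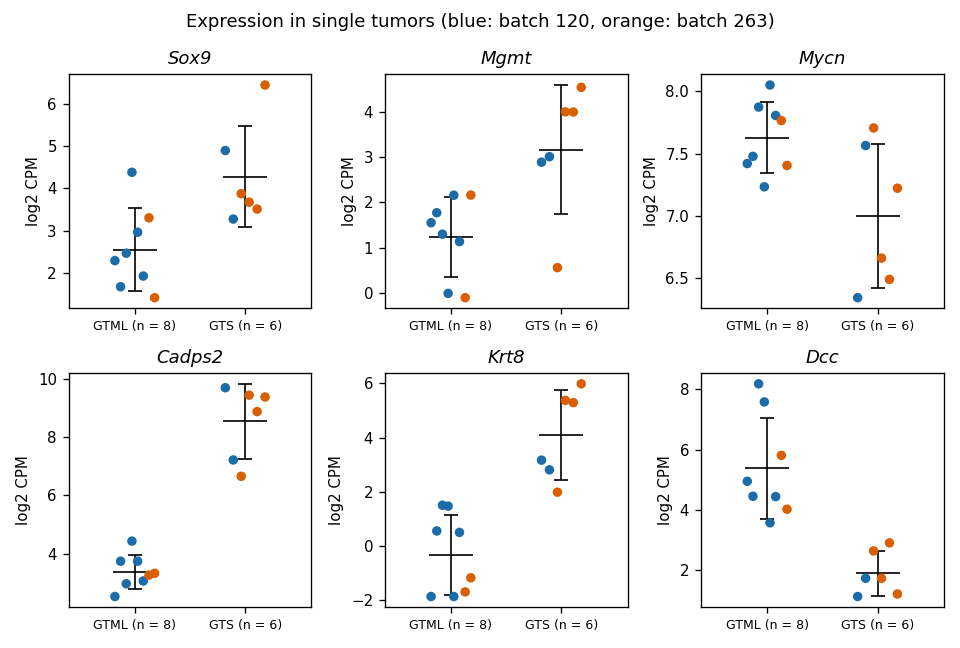
Log2 CPM of Sox9, Mgmt, Mycn, Cadps2, Krt8 and Dcc in each GTML (n = 8) and GTS (n = 6) tumor, with dots coloured by batch (blue, the batch of 8 tumors; orange, the batch of 6) and bars for the mean ± SD. Cadps2 and Krt8 lie above every GTML tumor in all 6 GTS tumors and Dcc below, as the rule that named them asked. The values of Sox9, Mgmt and Mycn, which were named in advance, overlap.

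DOX was compared with DMSO in GTML3. Mycn fell from 8.53 ± 0.139 to 4.94 ± 0.135 log2 CPM (SD, n = 3 each; log2 fold change -3.60, SE 0.15, limma adjusted p = 6.72e-11), and Sox9 rose from -0.47 ± 0.647 to 1.77 ± 0.329 (2.24, SE 0.325, adjusted p = 1.71e-05). Slc1a2 rose by 2.38 and Mgmt did not pass (-0.38, adjusted p = 0.105). Myc had 1 read under DMSO and 27 under DOX over the 3 libraries, a ratio of 38.7 with a counting interval of 6.39 to 1586. The largest increases were in Crtac1 (6.06), the acetylcholinesterase gene Ache (5.77), Amy1 (5.36), Loxl4 (5.28), the retinal calcium-binding protein gene Cabp5 (5.24) and Arhgef33 (5.16). The largest decreases were in the histone genes Hist1h3g (-4.28) and Hist1h1b (-3.95), Aunip (-4.11), the Mycn-related gene Mycs (-4.10), Phgdh, the first enzyme of serine synthesis (-4.02), and Kcnk5 (-3.95). Whether Mycs and Mycn share reads, in either line, was not tested. For each of these largest changes all 3 DOX samples lay beyond all 3 DMSO samples, which the rule for naming asked for.

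Growth and division genes fell together in GTML3. All 42 S-phase genes fell (median -2.75; Mcm6 -3.38, Mcm5 -3.36, Exo1 -3.61), as did 45 of 46 G2/M genes (median -2.75; Bub1b -3.10, Ccna2 -3.24) and 34 of 35 ribosome biogenesis and MYC target genes (median -1.83; Nolc1 -2.51, Dkc1 -2.82, and the spermidine synthase gene Srm -2.99). Of 27 DNA repair and drug resistance genes, 23 fell and 1 rose (Abcb1b -3.34, Chek2 -3.21, Tyms -2.99). Falls were also seen in 25 of 25 genes on the mitochondrial translation list (Hspd1 -2.52, Gfm1 -1.52) and 21 of 23 cholesterol synthesis genes, while 1 of the 23 rose (Sqle -1.61, Hsd17b7 -1.62). Photoreceptor genes rose in 11 of 13 cases and fell in 1, with the retinal transcription factor Crx at 4.16, Gngt2 at 3.3 and Prdm1 at 4.52. Neuronal differentiation genes rose in 20 of 31 cases and fell in 4, with Camk2b at 3.32 and the synaptic vesicle genes Syt1 at 3.52 and Syp at 2.68. All 20 lysosome and autophagy genes rose (Grn 2.36, Ctsd 1.32). Of 23 hypoxia and glycolysis genes 15 fell and 5 rose, with the glycolytic genes Eno1 at -2.58 and Pgam1 at -1.79 and Ndrg1 at 2.15. Of 20 ATF4 stress response genes 12 fell and 5 rose, with the one-carbon and serine genes Mthfd2 at -2.95 and Psat1 at -3.06. Adjusted over the list alone, the counts of these lists were the same. Camera called these 11 lists, and 8 held with an estimated correlation (adjusted p from 0.0195 to 0.0441). The calls of lysosome (adjusted p = 0.0761 with an estimated correlation), hypoxia (0.22) and ATF4 genes (0.245) did not. Of 15926 genes limma called 10484, 5487 up and 4997 down, and 10126 without replicate 1 under DOX, which stood apart from the other 2.

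In preGTS1, DOX lowered Mycn from 10.6 ± 0.243 to 5.77 ± 0.312 log2 CPM (n = 3 each; -4.86, SE 0.15, limma adjusted p = 2.22e-12) and raised Sox9 from 1.67 ± 0.538 to 3.80 ± 0.078 (2.13, SE 0.325, adjusted p = 2.65e-05). Mgmt rose from 2.08 ± 0.173 to 3.16 ± 0.378 (1.09, SE 0.2, adjusted p = 0.000169), Myc by 3.85 (84 reads to 955, adjusted p = 1.4e-05) and Slc1a2 by 2.26. The neuropeptide gene Nts went from 2 reads to 265 (191.8 times, counting interval 52.57 to 1592). Ecel1 rose by 7.32, the axonal adhesion gene Cntn2 by 5.82, Stmn2, a regulator of microtubules in growing axons, by 5.60, the neuronal chromatin subunit gene Actl6b by 5.55 and the proton channel gene Otop3 by 6.22. The largest decreases were in the carbonic anhydrase gene Car12 (-5.61), Mycs (-5.48), the 5.8S ribosomal RNA n-R5-8s1 (-5.21, adjusted p = 0.0175, lost without replicate 2 under DOX), Psrc1 (-4.94), the mitotic cyclin gene Ccnb2 (-4.92) and the lipoprotein lipase gene Lpl (-4.86).

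All 42 S-phase genes (median -3.16; Exo1 -3.82, Clspn -3.61), all 46 G2/M genes (median -3.37; Top2a -4.01, Bub1b -3.62) and 34 of 35 ribosome biogenesis genes (median -2.12; Dkc1 -3.50, Nop56 -2.60) fell in preGTS1. So did 24 of 27 DNA repair genes (Tyms -3.59) and 25 of 25 genes on the mitochondrial translation list (Timm10 -2.08). The same held for 21 of 23 cholesterol genes (Fdps -2.11, Insig1 -1.73) and 18 of 23 hypoxia and glycolysis genes (Ldha -3.10, Pgam1 -2.84). In the DNA repair, cholesterol and hypoxia lists 1, 1 and 2 genes rose. Neuronal differentiation genes rose in 27 of 31 cases and none fell (median 1.87; the transcription factor Nhlh1 4.08, Dpysl3 3.32, Stmn3 2.92), and matrix and mesenchymal genes in 12 of 19 with 1 fall (Col6a1 3.06, Lgals1 1.77, Zeb2 1.51). Of 6 mural and fibroblast markers, 4 rose and 0 fell (median 2.02, camera adjusted p = 0.103). Other lists rose with calls that were lost when the correlation was estimated. Astroglial genes rose in 19 of 30 cases and fell in 3 (Fabp7 3.39, Prdx6 -2.0; adjusted p = 0.0601 with an estimated correlation). Quiescence genes rose in 11 of 18 with 1 fall (the kinase inhibitor Cdkn1b 1.68, Btg1 1.32, Foxo3 1.22; adjusted p = 0.0601) and lysosome genes in 19 of 20 (Psap 1.48; adjusted p = 0.0799). Granule neuron progenitor and SHH genes rose in 8 of 17 with 1 fall (Zic2 2.01, Ptch1 1.19; adjusted p = 0.202) and Notch genes in 8 of 13 with 1 fall (Hes5 2.46, Notch1 1.71; adjusted p = 0.173). Photoreceptor genes rose in 9 of 13 with 3 falls (Pde6g 2.88, Crx 1.92; adjusted p = 0.067) and interferon genes in 8 of 13 with 1 fall (Ifi27 3.07, Cmpk2 1.44, Ifit2 -1.70; adjusted p = 0.0799). Over each list alone these counts were the same. Camera called 16 lists and 9 held with an estimated correlation (adjusted p from 0.00213 for neuronal genes to 0.0416 for hypoxia genes). Of 15926 genes limma called 10873, 5499 up and 5374 down.

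**Figure D2:**
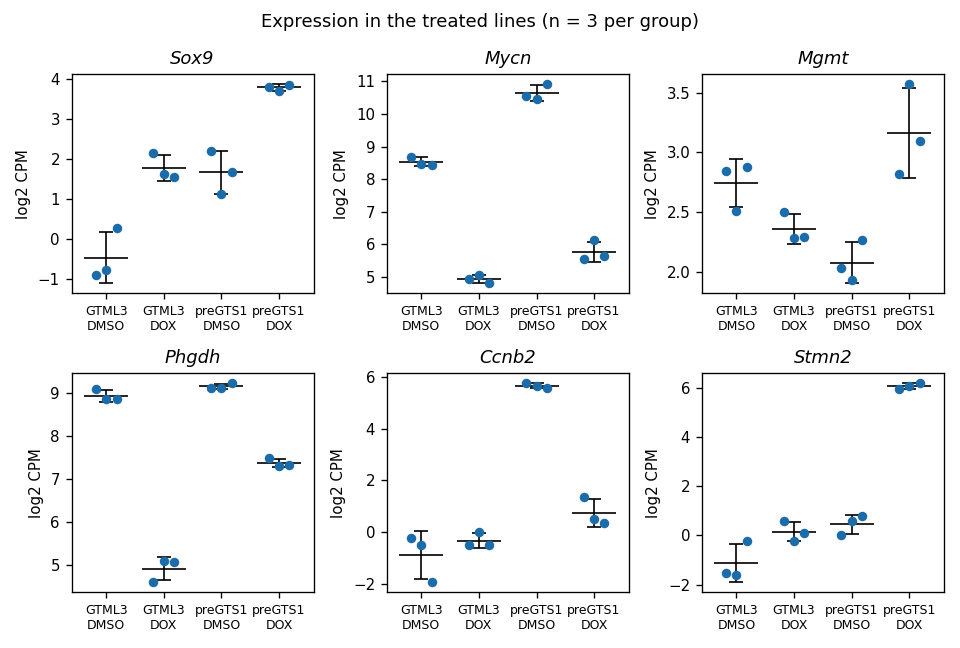
Log2 CPM of Sox9, Mycn, Mgmt, Phgdh, Ccnb2 and Stmn2 in GTML3 and preGTS1 under DMSO and DOX, each dot a sample (n = 3 per group) and bars the mean ± SD. Mycn falls from 8.53 to 4.94 in GTML3 and from 10.6 to 5.77 in preGTS1, while Mgmt rises in preGTS1 alone among the called changes.

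The responses of both lines were then compared through the interaction term of the limma fit (preGTS1 minus GTML3). Mycn fell further in preGTS1 (-1.27, SE 0.211, adjusted p = 0.000324) and Mgmt responded higher (1.47, SE 0.283, adjusted p = 0.000714). The Sox9 (-0.12, adjusted p = 0.858), Myc (-0.85, adjusted p = 0.403) and Slc1a2 (-0.12, adjusted p = 0.55) responses did not differ past the threshold. The Myc value turned positive with a pseudocount, since GTML3 had 1 Myc read under DMSO, and it passed the threshold without replicate 3 of GTML3 under DMSO. The responses of Nav3 (6.61), Fam83f (6.43), Scg5 (5.92), Fjx1 (5.72), Sema6d (5.62) and Olfml2b (5.08) were higher in preGTS1. For Nav3 the reads over 3 libraries went from 69 to 3 in GTML3 and from 383 to 1380 in preGTS1, and for the axon guidance gene Sema6d from 6 to 0 and from 1155 to 9124. Lower in preGTS1 were the responses of Lpl (-7.76; 2 reads to 12 and 2225 to 61), the corepressor gene Tle2 (-6.31; 147 to 731 and 1351 to 95), Fam92b (-6.159), the photoreceptor calcium sensor Guca1a (-6.03; 828 to 2497 and 52 to 3), Fkbp11 (-5.97) and Acsm4 (-5.76). Under DOX, Sema6d in GTML3 and Acsm4 in preGTS1 had 0 reads. Their fitted differences are not bounds, and size and rank depend on the value that stands for 0 reads.

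Neuronal differentiation genes responded higher in preGTS1 in 21 of 31 cases and lower in 2 (median 1.38; Nhlh2 2.73, Stmn3 2.22), matrix and mesenchymal genes in 12 of 19 and 0 (Lgals1 1.72, Col6a1 1.40), and ATF4 stress response genes in 14 of 20 and 0 (Phgdh 2.23, Psat1 2.13, Mthfd2 1.73). Photoreceptor genes responded lower in 11 of 13 cases and higher in 1 (Npr3 -4.80, Crx -2.24; Neurod1 1.67). These calls held with an estimated correlation (adjusted p = 0.00376, 0.0113, 0.0442 and 0.0343). Over the list alone, 22 neuronal and 15 ATF4 genes responded higher, and the other counts were the same. A further 9 lists called at the preset correlation did not hold. Among them were astroglial genes (12 higher and 2 lower of 30, Slc1a3 3.69, Id2 3.57, Nfib 2.75; adjusted p = 0.128 with an estimated correlation), Notch genes (7 of 13 higher, Notch1 3.26, Notch2 1.95; adjusted p = 0.112) and granule neuron progenitor genes (8 of 17 higher, 2 lower, Zic2 2.64; adjusted p = 0.128). Hypoxia genes responded lower in 14 of 23 cases and higher in 2 (Ldha -2.61, Ndrg1 -2.21; adjusted p = 0.128) and G2/M genes lower in 32 of 46 (adjusted p = 0.207). The G2/M gene Ccnb2 (-5.48) had 34 reads under both conditions in GTML3 and went from 3255 to 90 in preGTS1. The other 4 lists were ribosome biogenesis (20 of 35 lower; adjusted p = 0.17), S-phase (22 of 42 lower, 4 higher; adjusted p = 0.306), DNA repair (17 of 27 lower, 3 higher; adjusted p = 0.199) and mitochondrial translation genes (13 of 25 lower; adjusted p = 0.207). In all, 6721 of 15926 genes were called, 2718 higher and 4003 lower in preGTS1, with the median of all genes at -0.098. Of those called at 2-fold or more, 1458 were higher and 1193 lower, and DESeq2 on the recovered reads called 3206 higher and 3738 lower (46.2% higher, against 40.4%).

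Under DMSO, preGTS1 was compared with GTML3. Sox9 (2.14, SE 0.325, limma adjusted p = 2.97e-05) and Mycn (2.10, SE 0.15, adjusted p = 2.45e-08) were higher in preGTS1, and Mgmt (-0.67, adjusted p = 0.00828) and Slc1a2 (-0.71) lower. Myc had 84 reads in preGTS1 and 1 in GTML3 (64.25 times, counting interval 11.22 to 2568). Several genes were expressed in 1 line only at this depth. The linker histone gene H1f0 had 40074 reads against 1 (30650 times, 5501 to 1211000), and the glycine decarboxylase gene Gldc 227.6 CPM against 0 reads (at least 4233-fold higher). Also higher were Gnai2 at least 2316-fold, the collagen gene Col3a1 at least 2317-fold, Thbs2 at least 2234-fold, and the mitochondrial folate gene Aldh1l2 by 8357 times (10926 reads against 1; 1500 to 330100). In the other direction, Rhox2h was at least 861.1-fold higher in GTML3, Zscan4d at least 372.6-fold, Zscan4c at least 278-fold, Bpifb4 at least 242.3-fold, Nell1 had 5372 reads against 8 (877.9 times) and the muscle myosin chaperone gene Unc45b 2097 against 5 (548.3 times). Zscan4c, Zscan4d and their near-identical neighbours can share reads, so their values are uncertain.

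Matrix and mesenchymal genes were higher in preGTS1 in 16 of 19 cases and lower in 2, with Sparc at 5.07, the integrin gene Itgb1 at 3.24 and Twist1 at least 489.5-fold, and this call held with an estimated correlation (adjusted p = 0.0338). The calls of 6 further lists did not. Astroglial genes were higher in 26 of 30 cases and lower in 3 (Vim 7.07, Nes 5.11; adjusted p = 0.0723 with an estimated correlation). Also higher were Notch genes (9 of 13 higher; Notch1 5.23, Hes5 at least 477.1-fold; adjusted p = 0.191) and hypoxia and glycolysis genes (19 of 23 higher; Slc2a3 6.36, Pfkp 3.79; adjusted p = 0.136). The same was seen for ATF4 genes (17 of 20 higher; Cebpb 3.96, Nupr1 3.5; adjusted p = 0.151) and ribosome biogenesis genes (31 of 35 higher, 1 lower; Ppan 1.62; adjusted p = 0.151). Photoreceptor genes were lower in 9 of 13 cases and higher in 4 (Pde6g -5.62, Impg2 -3.01, Otx2 -2.65; adjusted p = 0.13). Over the list alone, 20 hypoxia genes were higher and the other counts were the same. In all, 10574 genes were called, 6124 higher and 4450 lower (57.9% higher). Quantile normalization, which moved the median gene from 0.126 to -0.036, gave 4917 and 5342 (47.9%).

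The RNA changes were compared across genes, which are not independent replicates. The DOX responses of GTML3 and preGTS1, which share no libraries, had a Spearman rho of 0.65 over 15926 genes: 3597 genes rose in both (1895 for independent lists), 3655 fell in both (1686) and 884 went opposite ways. The GTS minus GTML tumor difference had a rho of 0.275 with the GTML3 response and 0.293 with the preGTS1 response over 12287 genes. Among genes called in both, 264 were higher in GTS tumors and rose with DOX in GTML3 (160.8 for independent lists), 174 were lower and fell (90.29) and 88 went opposite ways. For preGTS1 these counts were 282 (149.8), 184 (104.3) and 86.

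Open chromatin was compared first between DOX and DMSO, with all coordinates in the authors' mm9 positions and each condition counted as 1 sample. At Mycn, a region within the gene body (chromosome 12, 12946846 to 12947329, 1555 bases from the start) went from 32.7 to 7.84 CPM in GTML3 (112 to 14 reads) and from 77.2 to 23.02 CPM in preGTS1 (limma adjusted p = 0.0243 and 0.0389). These calls were lost with a pseudocount of 0.25, without trend, and when either DMSO library of GTML3 or any library of preGTS1 was left out. As in RNA, ATAC values at Mycn do not separate the transgene from the mouse gene. The region at the start (12948420 to 12948933) was at 12.9 and 22.8 CPM in GTML3 and 18.2 and 28.9 in preGTS1 (adjusted p = 0.132 and 0.23). The region at the Sox9 start (chromosome 11, 112642601 to 112643930) held 42.0 and 44.1 CPM in GTML3 and 90.9 and 65.1 in preGTS1 (adjusted p = 0.885 and 0.14). The region at the Myc start (chromosome 15, 61816384 to 61817371) held 32.4 and 24.6 CPM, and 41.4 and 30.4 (adjusted p = 0.288 and 0.248). In preGTS1 the largest gains were near Zfp324 (chromosome 7, 13539960 to 13540687, 21.8-fold), Isx (24.4-fold), Phlpp1 (20.8-fold), Fnip2 (18.7-fold) and Vipr2 (16.3-fold). Among the largest losses were regions near Kirrel3 (12.8-fold), 6530403H02Rik (11.02-fold) and Nnt (12.6-fold), and near the germ cell gene Tex14 (chromosome 11, 87275767 to 87277589, from 131.7 to 16.1 CPM, 8.21-fold). In GTML3 the largest gain, near Rab28 (chromosome 5, 42076146 to 42077007), was from 0 reads to 24, at least 15.23-fold, and the largest loss, near Hsd17b13 (chromosome 5, 104382205 to 104383055), was at least 9.631-fold.

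Among the 44491 regions with the higher means, 4845 were 2-fold higher and 4247 2-fold lower under DOX in GTML3 (20.4%), where 17.2% and 29.99% differed that far between duplicates of 1 condition. In preGTS1 2857 were higher and 4611 lower (16.8%), against 0.883% and 1.41% between duplicates. Limma called 3486 regions in GTML3 (1685 gained, 1801 lost) and 3322 in preGTS1 (1813 and 1509), comparing libraries. These counts do not compare the extent of the responses, since 1 fit served libraries of unlike depth. In simulated data 55.1% of the GTML3 calls and 0 of 53 preGTS1 calls were unchanged regions. EdgeR called 3684 and 23985 regions. Limma called 1917 and 732 with a pseudocount of 0.25, 2580 and 6811 with quantile normalization, and 2822 and 1553 without trend. Without DMSO replicate 1 or 2 of GTML3 840 or 725 regions passed, and without its DOX replicate 1 or 2 8395 or 6142. In preGTS1 the counts were 161 and 172 without DMSO replicate 1 or 2 and 188 and 217 without DOX replicate 1 or 2. In regions called in both lines, 275 were gained in both (34.33 for independent lists), 383 lost in both (30.54) and 6 went opposite ways. The difference between the responses passed in 12 of 88981 regions (9813 at unadjusted p under 0.05). Higher in preGTS1 were 5 regions, near Igsf3 (4.77), Hjv (2.94), Kat6b (0.61), Ppp2r3d (0.54) and Rn45s (0.37), and lower were 7, among them regions near Abra (-3.23), Ripply1 (-2.77), Gm28590 (-2.61), Adgrl2 (-1.62) and Mreg (-1.10). Without trend the count was 0, and edgeR called 611. The value at Ppp2r3d turned to -0.079 with quantile normalization, and leaving out GTML3 DOX replicate 1 or 2 gave 1084 or 530 regions. Leaving out GTML3 DMSO replicate 1 or 2 gave 0 or 3, and any library of preGTS1 1 or 2. At promoters, photoreceptor genes had a median change of 0.50 in GTML3 (12 genes, at the 99.6th percentile of random lists) NF-kB genes 0.41 (12 genes, 99.7th), S-phase genes -0.23 (37 genes, 0.05th) and ATF4 stress response genes -0.44 (20 genes, below all random lists). Matrix genes stood at -0.41 (22 genes, 0.23rd) in GTML3 and -0.46 (below all random lists) in preGTS1, where 12 of 19 matrix genes had risen in RNA. The 22 and 19 genes are different parts of the list and were not matched gene by gene. Also outside the central 95% of random lists in preGTS1 were granule neuron progenitor genes (-0.34, 16 genes, 0.38th), Notch genes (-0.29, 10 genes, 1.62nd), S-phase genes (-0.11, 37 genes, 1.88th) and endothelial markers (0.55, 5 genes, 98.6th).

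Under DMSO, preGTS1 differed from GTML3 by 2-fold or more in 31.4% of the 44491 regions, 10385 higher and 3565 lower. Between duplicates, 0.883% differed that far in preGTS1 and 17.2% in GTML3. Higher in preGTS1 were regions at the start of Stxbp6 (chromosome 12, 46174378 to 46176356, 1235 reads against 2, ratio 145.2, counting interval 40.12 to 1201), Cldn34c1 (68.6-fold) and Slc30a10 (692 reads against 1, ratio 162.8, 29.12 to 6438). Others lay near Prdm8 (985 reads against 3, ratio 77.23, 26.35 to 375.1) and Tsga8 (at least 42.42-fold). Lower were 2 regions near the X-linked G530011O06Rik (134.2-fold and 88.1-fold), and others near Pde8b (69.6-fold), Xlr3c (3 reads against 121, ratio of GTML3 to preGTS1 171.5, 57.3 to 843.1) and Ghitm (42.7-fold). The Sox9 start region was 2.17-fold higher (90.9 against 42.0 CPM, adjusted p = 0.000423). Limma called 15773 regions, 10907 higher and 4866 lower (69.1% higher; quantile normalization, which moved the median region from 0.276 to -0.077, gave 6975 and 6034, 53.6%), and 9827 or 9378 without GTML3 replicate 1 or 2 and 5526 or 5647 without preGTS1 replicate 1 or 2. Of the regions lower in preGTS1, 55.5% lay within 1 kb of a gene start, against 12.8% of other regions, and of those higher 10.3%. Promoters of photoreceptor genes were more open in preGTS1 (median 0.94, 12 genes, 99.8th percentile of random lists), although 9 of 13 such genes were lower in RNA. The 12 and 13 genes are different parts of the list and were not matched gene by gene. Astroglial (0.27, 26 genes), oligodendrocyte (1.83, 6 genes), neuronal (0.25, 31 genes) and TGF-beta and BMP genes (0.64, 15 genes) also lay above the central 95%.

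The GTS sources were compared with GTML3 under DMSO. The Sox9 start region held 110.2 CPM in GTS1 and 71.7 in GTS2, against 42.0 in GTML3 (fitted log2 change over both sources 1.08, adjusted p = 3.667e-05). A region in the Mycn gene body (chromosome 12, 12944571 to 12945553) held 21.45 CPM in GTS1 and 39.2 in GTML3 (132 and 135 reads; GTML3 over GTS1 1.82, counting interval 1.42 to 2.33) and 0 reads in GTS2, at least 37.42-fold lower than GTML3. Its fitted log2 change over both sources was -3.03 (adjusted p = 4.052e-08). The region 1555 bases from the Mycn start held 68.0 CPM in GTS1, 6.27 in GTS2 and 32.7 in GTML3. Here too, values at Mycn do not separate the transgene from the mouse gene. Gains stood at the starts of Rab40b (chromosome 11, 121249161 to 121250143, 45.0 CPM in GTS1 and 68.25 in GTS2, against 0.286 in GTML3) and the transcription factor gene Dmrta2 (chromosome 4, 109650054 to 109650981, 60.2 and 63.6, against 0.572) and near Ltc4s, a leukotriene synthesis gene (24.15 and 97.55, against 0.299). Losses lay near Scml4 (0.24 and 1.21 CPM, against 99.8), Fam110b (0.74 and 0.302, against 93.1), Ghitm (1.48 CPM and 0 reads, against 90.0) and the ephrin receptor gene Epha5 (2.46 and 1.87, against 170.6). GTS1 and GTS2 differed as much from each other (48.3% of 44491 regions by 2-fold) as from GTML3 (47.0% and 53.4%), and 3192 regions were higher and 8717 lower in both. Between duplicates, 9.95% of regions differed that far in GTS1, 22.4% in GTS2 and 17.2% in GTML3 under DMSO. Part of the shares between sources can thus be counting noise. Promoters of photoreceptor genes were lower in both sources (medians -0.89 and -0.91, at percentiles 0.1 and 0.27), whereas those of astroglial genes had a median of 0.89 in GTS1 (percentile 99.96) and -0.46 in GTS2 (0.53). In GTS1 the medians of NF-kB (0.92), TGF-beta and BMP (1.25), ATF4 (0.46) and p53 target genes (0.37) and in GTS2 those of quiescence (0.50), p53 target (0.55) and mitochondrial translation genes (0.54) lay above the central 95% of random lists, and that of neuronal genes in GTS2 (-1.02) below all of them. Limma called 34876 regions, 17157 higher and 17719 lower.

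GFP and nonGFP fractions, which the labels do not define further, were compared within their own table. At Sox9, the start region (chromosome 11, 112642514 to 112644480) held 182.6 CPM in GFP and 101.2 in nonGFP (1.80-fold, counting interval 1.71 to 1.89, adjusted p = 1.759e-53), and a second region inside the gene (112646239 to 112646686) 20.3 and 9.95 CPM (2.04-fold, 1.75 to 2.39, adjusted p = 1.1e-07). At Mgmt (chromosome 7, 144079811 to 144080905) the values were 17.7 and 22.5 CPM (adjusted p = 0.139), and Mycn and Myc regions did not pass. The largest gains were near the cadherin gene Cdh6 (21.5-fold), Plekhb2 (12.3-fold), Has2as (11.5-fold), Gpr125 (10.7-fold) and E130114P18Rik (8.03-fold), and the largest losses near Kif2b (2.87-fold), Cyp20a1 (2.37-fold), Pla2r1 (2.33-fold), Mirlet7i (2.26-fold) and Hgf (2.06-fold). Among 44129 regions 174 were 2-fold higher and 6 lower (0.408%), against 0.0453% and 0.034% between duplicates. Limma called 3047, 2048 gained and 999 lost, but 0 without the trend in its variance (11430 at unadjusted p under 0.05; 3222 by edgeR). Without GFP replicate 1 or nonGFP replicate 1 or 2 it called 1347, 857 or 1252. Promoters of astroglial (0.069, 25 genes) and TGF-beta and BMP genes (0.065, 14 genes) had medians above the central 95% of random lists. These lists share Id1, Id2 and Id3, the astroglial list holds Sox9 itself, and the percentiles were not adjusted over lists. Of the lost regions 30.5% and of the gained 8.45% lay within 1 kb of a start.

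Promoter accessibility and RNA were set side by side for 9972 genes with a region within 1 kb of the start. Across genes, Spearman's rho was 0.151 for the DOX response of GTML3, 0.0999 for that of preGTS1 and 0.43 for the difference between the lines under DMSO. Among genes called in both measures, 64.1%, 59.0% and 76.9% changed in the same direction (Fisher's exact p = 9.534e-08, 0.000127 and 1.244e-160, with odds ratios of 3.65, 2.11 and 19.2). Fisher's test takes genes as independent replicates, which they are not, so these p-values may be too small. In simulated data 55.1% of the GTML3 ATAC calls were unchanged regions.

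In single cells, Sox9 was found in more cells of fGTS2 than of GTML_SOX9GFP. After thinning to 3000 UMIs, which left out 71 and 35 shallower cells, 18.1% of 4427 fGTS2 cells (17.0 to 19.3) and 3.10% of 4610 GTML_SOX9GFP cells (2.62 to 3.64) had a Sox9 UMI, and without thinning 66.0% and 13.1%. Summed over all cells, Sox9 reached 68.6 CPM (67.0 to 70.2) and 12.2 CPM (11.5 to 12.9), a ratio of 5.64. Mgmt was found in 8.09% and 0.109% of thinned cells (39.7% and 0.667% unthinned; 27.7 and 0.334 CPM), Mycn in 13.1% and 17.9% (56.9% and 61.3%; 48.4 and 65.0 CPM), and the proliferation marker Mki67 in 24.7% and 34.8% (52.8% and 66.7%; 153.3 and 225.6 CPM). Slc1a2 was found in 1.04% and 8.94% (7.94% and 40.6% unthinned; 3.84 and 33.1 CPM). As a possible background level, 1.49% of the 67 neuronal-lineage-like cells of GTML_SOX9GFP (0.0378 to 8.04, median 17827 UMIs) had a Sox9 UMI. Neurons should lack Sox9, but these cells were not shown to be a type apart. Mki67 was found in 31.3% of them, and the neuronal gene Elavl3 stood at 197.4 CPM in the cycling-like cells of the library. The interval of the Sox9 share of the neuronal-lineage-like cells includes the share of the whole library (median 18744 UMIs). It is too wide to set the library apart from background. Summed over all UMIs, Sox9 stood at 2.37 CPM in these cells (0.489 to 6.92), below the 12.2 CPM of the library, and among clusters of over 50 cells it was highest in cluster 6 at 25.8 CPM (20.96 to 31.5). Cluster 5 of this library, left out of that ranking with 8 cells, had Sox9 among its leading genes by fold, beside Krt8, Alox5ap and Sh2d6. Cluster 6 need not be the highest of all clusters. No cell type that should lack Sox9 was found in fGTS2, so its background was not measured; the share differed between its clusters, from 12.2% to 29.6%.

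Cells with and without Sox9 were compared within each library. In fGTS2, 46.3% of cells with a Sox9 UMI (42.8 to 49.8) and 56.4% of cells without (54.7 to 58.0) had at least 3 cycling markers after thinning, and 21.8% and 25.4% had Mki67. In GTML_SOX9GFP these were 74.8% (66.9 to 81.7) and 72.5% (71.2 to 73.8), and 32.9% and 34.9%. No direction is read there, since at 1500 UMIs the shares with 3 cycling markers were 49.4% and 55.5%, and with 2 Sox9 counts 58.8% (32.9 to 81.6, 17 cells) and 72.6%. In fGTS2 they were 28.4% (20.2 to 37.9) and 55.2% with 2 Sox9 counts. Unthinned, the shares with 3 cycling markers were 86.9% and 87.6% in fGTS2, and 96.2% and 93.4% in GTML_SOX9GFP. The unthinned Mki67 shares were 53.3% and 51.7% in fGTS2, the other way from the thinned ones, and 74.0% and 65.6% in GTML_SOX9GFP. Unthinned cells with Sox9 were deeper (median 22188 against 19166 UMIs in fGTS2). Thinned cells without a Sox9 UMI need not lack Sox9. In fGTS2, 802 of 4427 cells had a Sox9 UMI after thinning and 2969 of 4498 unthinned. Clustering put no cluster in both libraries, so a cluster can be a library rather than a type. Cycling-like cells made up 19.1% of GTML_SOX9GFP (18.02 to 20.3, all in cluster 2) and 15.2% of fGTS2 (14.2 to 16.3, all in cluster 11). Neuronal-lineage-like cells made up 1.44% of GTML_SOX9GFP and 0 of 4498 in fGTS2. A class is given to a whole cluster by fold over the rest of its library. Rare neuronal cells inside an fGTS2 cluster, or neuronal genes shared across GTML_SOX9GFP, would thus go uncounted. At a clustering resolution of 0.5, the cycling-like share was 34.3% in GTML_SOX9GFP and 19.3% in fGTS2. The class does not hold all cells with cycling genes: Mki67 was found in 52.7% of cells of the unnamed cluster 3, with Aurkb, Cdk1 and Top2a among its leading genes, in 32.4% of cluster 4, led by S-phase genes such as Mcm4, and in 50.3% of the fGTS2 cluster 12. Of the fGTS2 clusters, cluster 14 had the most cells with Sox9 (29.6%, 26.6 to 32.8) and the fewest with Mki67 (1.97%, 1.15 to 3.14), while cluster 11 had 17.8% and 66.6%.

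Ratios between the single-cell libraries were taken over all cells and then within the cycling-like clusters. The keratin gene Krt18 had 49230 UMIs in fGTS2 and 7 in GTML_SOX9GFP (476.7 against 0.0731 CPM), Vamp8 7898 and 3 (ratio 2442, counting interval 835.5 to 11850), Armcx3 3153 and 6, Hebp1 2844 and 6, and Nxf3 2780 and 6. The ratios of Hist1h1a (786.4, 268.8 to 3816), Htatip2 (666.1, 227.6 to 3233) and Ctsz (306.2, 104.5 to 1487) rest on 3 UMIs in GTML_SOX9GFP each. The other way, the neuronal trafficking gene Nsg1 was 954.4 times higher in GTML_SOX9GFP, Zfhx4 910.3, Zmat4 738.1, the metabotropic glutamate receptor gene Grm5 488.3 and Ttc9b 476 times, with Epha5 (525.6, 179.5 to 2552), Galnt9 (520.6, 177.8 to 2527) and Tspan7 (447, 152.6 to 2170). Within the cycling-like clusters Krt8 was 1531 times and Trp53, the p53 gene, 311.5 times higher in fGTS2 (1642 UMIs against 5), Vamp8 at least 469.8-fold and Tagln2 229.6 times. The neuronal genes Elavl3 and Stmn3 were 553.5 and 515.6 times higher in GTML_SOX9GFP, Sept3 413.7 times and Ttc9b at least 353.2-fold.

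**Figure D3:**
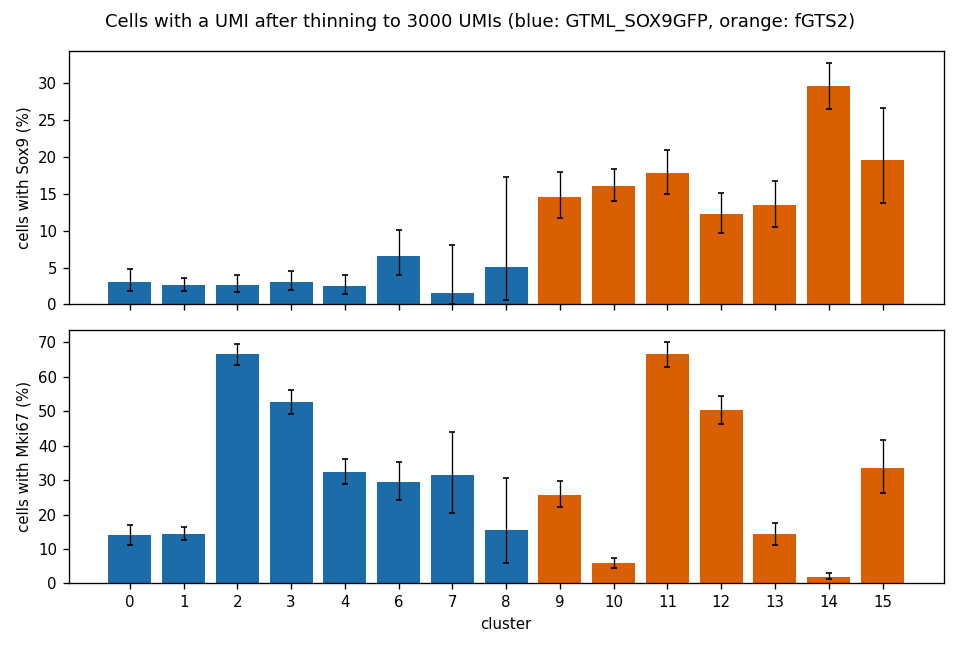
Percent of cells with a Sox9 UMI (top) and with an Mki67 UMI (bottom) in each single-cell cluster after thinning to 3000 UMIs, with exact 95% binomial intervals, for GTML_SOX9GFP clusters (blue) and fGTS2 clusters (orange); cluster 5, with 8 cells, is not drawn. Sox9 is highest in fGTS2 cluster 14 at 29.6%, where Mki67 is lowest at 1.97%.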

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

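All tests of explanations given here were chosen after the results were seen. Among the genes named for the tumors, 104 groups of values were searched for a tumor set apart from the others of its kind, and 8 were found. The critical value used lets chance find about 1 in 20 among normal values, a rate not tested on these genes, which were chosen by their tumor differences or lists. GTS tumor 1 was lowest in Fgd1 (-1.938 log2 CPM), Foxp3 (-2.451), Rcor2 (2.376) and the histone gene Hist1h4f (0.872). GTS tumor 2 was highest in Cad (8.116). GTML tumor 3 was highest in Foxp3 (6.573) and Rcor2 (9.296), and GTML tumor 8 in Nr1h5 (8.043).

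The DOX responses of GTML3 and preGTS1 differed, by the interaction term of limma, in 6721 genes and in 12 regions of open chromatin. Mycn fell further in preGTS1 (-1.268) and Mgmt responded higher (1.47). The largest differences toward preGTS1 were in Nav3 (6.609), Fam83f (6.433), Scg5 (5.919), Fjx1 (5.722), Sema6d (5.62) and Olfml2b (5.08), and toward GTML3 in Lpl (-7.763), Tle2 (-6.308), Fam92b (-6.159), Guca1a (-6.032), Fkbp11 (-5.965) and Acsm4 (-5.757). Those of Sema6d and Acsm4 stand beside 0 reads under DOX in 1 line, so their size and rank are uncertain. Median differences were 1.375 for neuronal differentiation genes, -1.008 for photoreceptor genes, 1.253 for matrix and mesenchymal genes and 0.8942 for ATF4 stress response genes. Of 100 splits of the treatment labels within the lines, drawn from 200, 1.0 (the real one) called as many genes. The highest other split called 5626 genes, and it left the labels in place in 6 of 6 preGTS1 samples and 4 of 6 GTML3 samples. Such splits do not show what equal responses of both lines would give, so they do not decide whether chance can be excluded.

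The 924 genes called between GTS and GTML tumors were weighed against 2 explanations. Of 100 splits drawn from 3003, 1.0, the real one, called as many, and the highest other called 1, but the batch removal kept tumor kind and no other split, which favours the real one, so the splits do not decide whether chance can be excluded. The split by batch called 0 genes by limma. A candidate explanation for the size of the count is that this removal lowered the spread between libraries. With a term for the batch, 9.0 genes passed, while the log2 folds of Cadps2 (5.15) and Krt8 (4.43) stayed as they were. The calls lost are not thereby shown to be unchanged genes. At unadjusted limma p under 0.05 there were 3067 genes with the term and 4253 without. In simulated data the term lowered the calls from 169 to 117, of which 26 and 1 were unchanged genes. For the calls lost, the difference between tumor kinds that the design names remains open, as untested.

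For the comparisons of 3 against 3 samples, the 10 possible splits are too few for a share under 0.05. DOX against DMSO called 10484 genes in GTML3, with 6 in the highest other split, and 10873 in preGTS1, with 1. Under DMSO, preGTS1 against GTML3 called 10574, with 0 in the highest other split. In each of the 3, only 1.0 split, the real one, reached the count.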

How the results depend on the processing

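The pseudocount of 1 on log2 RNA values, each tumor batch alone, gene lists with a batch term or replicate block, and edgeR and DESeq2 on recovered reads were tried after the data had been seen, and the other alternatives were planned. Where a value moved, the cause was not tested unless stated. The count of 924 genes between tumor kinds fell to 9 with a batch term, which spends the error that the batch removal had hidden, and to 514 with median-centred values. Within each batch alone limma called 0 genes (2149 and 2891 at unadjusted p under 0.05), and leaving out single tumors gave 110 to 1530. The RNA counts of the treated lines moved little: leaving out single samples gave 9757 to 10126 genes for GTML3, 10073 to 10534 for preGTS1, 5851 to 6871 for the difference of the responses and 9827 to 10006 under DMSO, and edgeR called 10627, 11404, 6906 and 10777. Open chromatin depended more on the settings, and its duplicates and depth limit it. With a pseudocount of 0.25, limma called 1917 regions for DOX in GTML3, 732 in preGTS1, 4 for the difference of the responses and 9227 under DMSO. Quantile normalization gave 6811 in preGTS1 and 35 for the difference. Without trend, counts were 1553 in preGTS1, 0 for the difference (10106 at unadjusted p under 0.05) and 0 between GFP and nonGFP (11430; 3222 by edgeR). EdgeR called 23985 regions in preGTS1 and 611 for the difference, and the upper part of the regions by mean gave 25. Leaving out single libraries gave 725 to 8395 regions in GTML3, 161 to 217 in preGTS1, 0 to 1084 for the difference, 25191 to 33855 for the GTS sources, 5526 to 9827 under DMSO and 857 to 2541 for GFP; a group then left with 1 library was assumed to vary like the others. Replicate numbers did not pair the samples: the deviations of same-numbered RNA samples correlated by -0.555 to 0.254 and those of ATAC libraries by -0.011 to 0.011. With a replicate block limma called 10211 (GTML3), 10615 (preGTS1), 6155 (difference) and 10253 genes (DMSO), and 3203, 3088, 9 and 15549 regions, 34675 for the GTS sources and 3132 for GFP. Of the gene lists, 0 were called in the tumors with an estimated correlation and 4 by fry, 21 by fry in GTML3, 9 with an estimated correlation in preGTS1, 4 for the difference and 1 under DMSO, where fry called 23. With a replicate block and an estimated correlation, calls were lost for ATF4 and photoreceptor genes in the difference (adjusted p = 0.0596 each), matrix genes under DMSO (0.0883), matrix (0.0561) and hypoxia genes (0.0741) in preGTS1, and neuronal, DNA repair and mitochondrial translation genes in GTML3 (0.0561 each). Cycling-like cells made up 34.27% and 19.3% of GTML_SOX9GFP and fGTS2 at resolution 0.5, 25.94% and 14.07% at resolution 2, 21.06% of GTML_SOX9GFP without called doublets and 17.63% of fGTS2 with at least 1000 genes per cell. Cells with Sox9 made up 0.3688% and 2.462% when 2 counts were asked for, 1.787% and 10.7% when thinned to 1500 UMIs and 13.07% and 66.01% unthinned. Among cells with Sox9, 58.82% and 28.44% cycled with 2 counts, 49.4% and 31.38% at 1500 UMIs and 96.21% and 86.93% unthinned; among cells without, 55.5% and 42.52% at 1500 and 93.44% and 87.64% unthinned. The sign turned for the Myc difference of responses (1.995 with a pseudocount of 0.25 and 2.448 with 1, against -0.845, on 1 read in GTML3 under DMSO) and for the region near Ppp2r3d (-0.079 with quantile normalization). Over all alternatives, 241 of 1265 fits of 55 tumor genes that the rule chose lost the call and 17 gained it. The same held for 6 and 2 of 3355 fits of 205 treated-line results chosen so, and for 133 and 10 of 1188 fits of 108 regions.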

Other observations

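The tests of explanations given here, the list of tuft-cell markers and the genes picked below were chosen after the data had been seen. Under DMSO and DOX, 16 genes had 0 reads in every GTML3 RNA library and at least 20 CPM in preGTS1 under at least 1 condition. Among them were the glycine cleavage gene Gldc (227.6 CPM under DMSO), S100a10 (76.2), the metallothionein gene Mt1 (35.7), the mesenchymal transcription factor gene Twist1 (26.3), the Notch target Hes5 (25.7) and the chemokine receptor gene Cxcr4, at 8.80 CPM under DMSO and 66.9 under DOX. Of these genes, 10 had a region within 1 kb of the start, and all 10 held fewer ATAC CPM in GTML3 than in preGTS1. The ratio was 15.7 at the potassium channel gene Kcnt2 (counting interval 9.77 to 27.1), 13.8 at Mt1 (7.20 to 30.3), 13.3 at Gldc (5.12 to 49.2), 5.62 at Cxcr4 (4.13 to 7.85) and 4.39 at Twist1 (2.26 to 9.77). At S100a10 and Thy1 the interval included 1. The reverse held for 3 genes, Rhox2h, Zscan4d and Zscan4f, and the region at Rhox2h was 51.9 times higher in GTML3 (21.1 to 165.4).

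Genes of tuft cells, chemosensory epithelial cells that carry a taste-like signalling cascade, were expressed in tumors and single cells. Of 17 listed markers, 15 were tested in the tumors, 6 were higher in GTS by limma, among them Hepacam2 (4.95), Krt8 (4.43), Alox5ap (2.89) and Sh2d6 (2.35), and 0 lower, with a median log2 fold change of 2.894. The list was written after Hepacam2 and Krt8 had been seen among the leading tumor genes. With a batch term 0 of the 15 passed in limma (13 at unadjusted p under 0.05), and the adjusted p was 0.0669 for Krt8, 0.073 for Hepacam2, 0.0774 for Alox5ap and 0.134 for Sh2d6. The median log2 CPM over the list in GTS tumors 1 to 6 was 3.003, 2.822, 2.592, 5.489, 5.903 and 7.143, and in GTML tumors it ran from -0.016 to 2.59. In single cells the tuft regulator Pou2f3 stood at 60.9 CPM in GTML_SOX9GFP and 45.8 in fGTS2, the taste channel gene Trpm5 at 38.4 and 93.2, the G protein subunit genes Gng13 at 575.4 and 726.5 and Gnat3 at 410.1 and 23.9, and Rgs13 at 484.9 and 211.4. In the neuronal-lineage-like cluster of GTML_SOX9GFP, Pou2f3 was lower, at 9.47 CPM (4.90 to 16.6).

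Technical explanations for these tuft-cell genes were weighed. In GTML_SOX9GFP, a few admixed tuft cells and their free RNA are argued against, since 10 listed genes were 2.319 to 10.06 times higher in cycling-like than in neuronal-lineage-like cells, and a Gng13 UMI was found in 64.9% (61.7 to 68.0) and 14.9% (7.40 to 25.7) of them after thinning. In fGTS2, 80.44% of cycling-like cells had a Gng13 UMI, but no cell type gave the background, so admixture stays open there. Free RNA from 1 source would hold Gnat3 and Gng13 in 1 ratio in every cluster. The ratio ran from 0.1326 in cluster 6 to 1.015 in cluster 4 of GTML_SOX9GFP (7.659-fold). In fGTS2 it ran from 0.02188 in cluster 10 to 0.05741 in cluster 9 (2.624-fold). These values argue against such free RNA as the only origin in all clusters of a library. They do not show which of the other clusters express the genes. In the tumors a batch effect stays open: the list medians of GTS and GTML tumors differed by 0.849 in the batch of 8 tumors and 5.232 in the batch of 6, and without Hepacam2 and Krt8 by 0.351 (pooled SD 0.54) and 4.793 (1.713).

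Cluster 6 of GTML_SOX9GFP, with 289 cells, held Trp53 at 51.6 CPM (44.7 to 59.4), against at most 0.638 in any other cluster of that library, and Trp53 is among the genes that set it apart. Cells of fGTS2 mixed into the library are argued against by 41 genes at least 20 times higher in fGTS2 than in the other GTML_SOX9GFP cells: for 13 of them the upper counting bound in cluster 6 was under 10% of their level in every fGTS2 cluster of at least 50 cells, among them Krt18, Krt8 and Tagln2 (476.7, 350.2 and 197.2 CPM in fGTS2) at 0 UMIs and Plac8 (545.2) at 10. The median was 9.86% of the fGTS2 level, against 85.0% to 142.1% in those fGTS2 clusters, although 10 genes, among them Mgst3, Tspan6 and Lmo2, reached 50% or more. Doublets are argued against by its median UMI count, which was 0.6353 times that of the other cells, and another cell type by the tuft-cell genes, whose median ratio to the rest was 0.8193 over 10 genes (0.159 to 1.45). What these cells are stays open, and no biological explanation was tested; Mgmt stood at 3.95 CPM in them against 0.185 in the rest, and Sox9 at 25.8 against 11.6.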
